A study of Rattus norvegicus with 6 samples.

How the data were processed

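RNA was measured in 6 trigeminal ganglion samples, 3 sham and 3 CCI-ION, grouped by the treatment and title given in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. Per the submitters' processing notes, cutadapt 1.14, Bowtie 1.1.1 and genome build rn6 were used. The read counter, annotation, strand setting and normalization tool are not given in the sources used here. The labels give separate samples and the series design gives n = 3, with no statement on pooling, so p-values measure the spread between these samples.

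The authors deposited 1 table per sample, with a gene symbol and a normalised signal in each of 47061 rows. From the values, this signal is the number of reads divided by 1 size factor per library: 100% of values in each library were whole multiples of the value of 1 read, within 0.01 reads. The size factors given by the value of 1 read were 0.900 to 1.16. Size factors were also computed from the recovered reads. Their product with the value of 1 read departed from its mean by at most 0.0487%. The tables held 17108 symbols, of which 9629 had more than 1 row (up to 49) with no transcript identifier, and 2047 rows repeated an earlier row in full. Each symbol was represented by its row with the highest mean, a choice made after the data were seen. Symbols turned into dates numbered 12 and were left as they stood. Of the symbols, 14840 matched a current symbol of the NCBI RefSeq gene table of assembly GRCr8, 790 only a synonym and 1478 none. As the build differs from rn6, no coordinates were used, and list members were matched by exact symbol. All rows carried a symbol, and no column of values was left unused.

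Depth was 42988262 to 55439086 reads per library over all rows, which can count a read once for each transcript, and 16591649 to 21215357 with 1 row per symbol. The 10 most abundant symbols took 6.13% to 8.17% of reads. Haemoglobin genes took 0.0521% to 0.0828%. Counting intervals are exact conditional 95% intervals and, like the floor of 3 reads per group, cover counting error only. The value of 3 reads was 2.59 to 3.33 normalised counts.

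The following were fixed before the data were examined: the groups, the test, the gene lists, the rule for named genes and most of the alternatives. The written design provided limma for FPKM, RPKM, TPM or CPM, and it was applied here to counts divided by size factors, since the deposited values were normalised. Genes with a value of at least 1 in 3 or more samples were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust) on log2(value + 1), two-sided, without covariates, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Gene lists were tested with camera of limma at a preset correlation of 0.01, Benjamini-Hochberg adjusted over 32 lists, and beside it with an estimated correlation and with fry. Of 34 lists, that of sex-linked genes had no set test by design and that of mitochondrially encoded genes had no measured member. The lists covered the study axis, nerve injury response, voltage-gated potassium, other potassium, sodium, and calcium and HCN channels, inhibitory and opioid receptors, markers of nociceptors, large-fibre neurons, neurons in general, satellite glia, myelinating and repair Schwann cells, macrophages, lymphocytes, neutrophils, mast cells, fibroblasts and matrix, vessels, muscle, pituitary, central oligodendrocytes and blood, and cytokines, interferon-stimulated genes, complement, cell cycle, immediate-early, heat shock, cholesterol, respiratory chain, mitochondrial, ribosomal and sex-linked genes.

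Named genes were those of the series title, the 12 higher and 12 lower genes with the largest fold among those past the threshold with a mean of at least 1 on the log2 scale and no overlap between groups, and up to 4 members of each list in order of p. Locus-number symbols were counted, not named (126 past the threshold). A further 46 genes were named after their values were seen, mostly the remaining members where a list had 5 or fewer calls in a direction, and genes of the central glia and of lists written after the values were seen. Foxa2, for which no row was used, was not analysed here. Some genes that these rules select are not reported here, so a list with few calls can have members without a name.

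Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5, quantile normalization, centring of libraries, eBayes without trend and robust, a replicate block, leaving out each library, a fold of at least 2, and adjusted p below 0.1. On the recovered reads, edgeR 4.0.16 (quasi-likelihood with TMM, with DESeq2 size factors, with library totals, without a filter and with a stricter filter), DESeq2 1.42.0 and limma-voom were run; edgeR with TMM called 2736 genes. Chosen after the data were seen were the mean, sum or first row per symbol, testing each row, leaving out CCI-ION 1 and 2 together, and the mean log2 level of central oligodendrocyte markers as a covariate. The test was checked on simulated counts for these samples, in 3 runs with 200 changed genes each. Of genes changed 1.3-fold 36.0% were recovered, 79.3% at 1.5-fold, 83.3% at 2-fold and 96.7% at 4-fold, and 31 of 474 calls were false. The changed genes were drawn only from genes above a minimum mean count, so these recovery rates do not cover genes with few reads. Camera called 3 of 3 altered lists and 0 others. The simulated genes were drawn independently, so this check cannot tell how camera treats lists whose members move together. In these samples the estimated correlation was 0.848 for ribosomal proteins and 0.304 for macrophage markers. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.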

Results

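Whole trigeminal ganglia of Sprague-Dawley rats were profiled by sequencing of polyadenylated RNA on day 14 after surgery. The 3 CCI-ION libraries came from rats with a chronic constriction injury of the infraorbital nerve, a facial branch of the trigeminal nerve, made with loose silk ligatures. The 3 sham libraries came from rats in which the nerve was only exposed. With 1 row kept per gene, the libraries held 20530198, 17655686 and 21215357 reads in sham 1 to 3 and 17766927, 17829335 and 16591649 in CCI-ION 1 to 3, and between 16758 and 16867 gene symbols had at least 1 read. Pearson's r across genes, which are not independent replicates, was 0.985 to 0.988 between libraries of the same group and 0.973 to 0.978 between groups. The first principal component held 46.1% of the variance and separated the groups. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 7.10 to 10.2 within groups). Values below are normalised read counts as mean ± SD with n = 3 per group, and fold changes are log2 differences of CCI-ION minus sham on the log2(value + 1) scale, which understates changes of low genes.

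The comparison asked how nerve injury changed gene expression in the ganglion, and what happened to the gene of the protein arginine methyltransferase PRMT2, named in the series title, and of its family. Injury-response genes were much higher in CCI-ION ganglia: Atf3, a stress-induced transcription factor, rose from 146 ± 8.01 to 3347 ± 60.3, and Cacna2d1, the calcium channel subunit bound by gabapentin, rose from 2038 ± 88.6 to 8695 ± 401. Genes of macrophages rose as well, with Cd74, the class II invariant chain, going from 1613 ± 282 to 9943 ± 1651. The potassium channel gene Kcna2 (Kv1.2) fell from 11910.2 ± 481 to 7186 ± 179.6, and the sodium channel gene Scn11a (Nav1.9) from 5566 ± 46.0 to 3962 ± 306. Nefm, a neurofilament gene of large-fibre neurons, fell from 204095 ± 2513 to 133279 ± 3387. In these genes each CCI-ION library lay on the same side of each sham library, and limma adjusted p was 1.65e-14 for Atf3, 2.49e-11 for Cacna2d1, 4.68e-05 for Cd74, 1.32e-06 for Kcna2, 1.37e-04 for Scn11a and 8.76e-06 for Nefm.

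**Figure D1:**
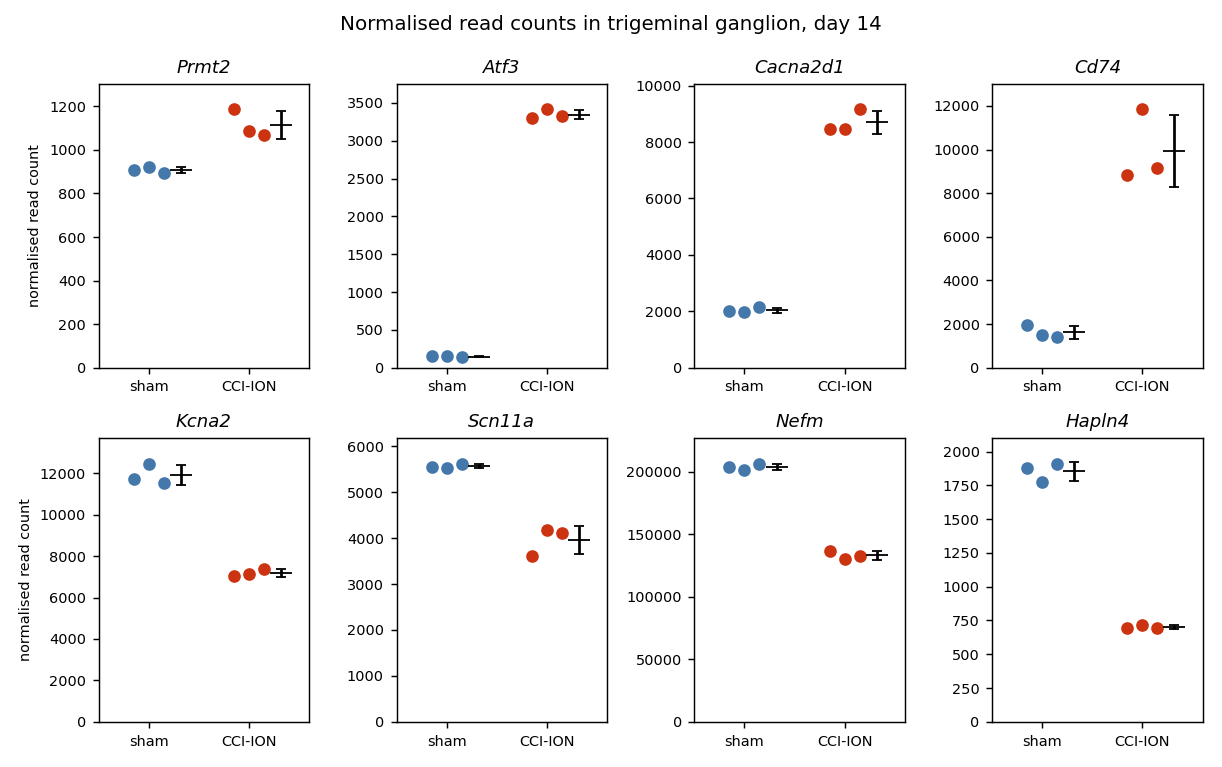
Normalised read counts of 8 genes in each library (points, sham blue, CCI-ION red), with the group mean and SD (black bars, n = 3) on axes that start at 0. Atf3, Cacna2d1, Cd74 and Prmt2 lie higher in CCI-ION, and Kcna2, Scn11a, Nefm and Hapln4 lie lower, with no overlap between the groups.

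Prmt2 rose by 22.7%, from 908 ± 12.2 to 1114 ± 63.0 (log2 fold change 0.29, SE 0.07, limma adjusted p = 0.0101). Each CCI-ION library lay above each sham library, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Of the other arginine methyltransferase and Foxa genes measured, Prmt8, a methyltransferase of neurons, fell from 169 ± 17.8 to 104 ± 26.1 (−0.73, limma adjusted p = 0.0138), and 7 did not pass. Adjusted over the study axis list of 10 genes alone, Prmt2 had limma adjusted p = 0.00646, but the study chose this gene, so this is not independent evidence. The list as a whole did not pass (camera adjusted p = 0.872, and adjusted p = 0.953 with an estimated correlation), and the calls were the same adjusted over the list alone. Its median was 0.002, its mean −0.07 and its test pointed down, and the median was −0.01 after quantile normalization and −0.02 after centring. Leaving out 1 library ended the call of Prmt8 without sham 3 or CCI-ION 2 (adjusted p 0.0520 to 0.0651), and Prmt2 kept its call without any 1 library. With CCI-ION 1 and 2 left out together, an alternative chosen after the data were seen, Prmt2 had a log2 fold change of 0.24 (adjusted p = 0.264). Its call also ended without the trend and robust settings (adjusted p = 0.0662) and with the central oligodendrocyte level as a covariate (adjusted p = 0.0888), and over all alternatives its adjusted p ran from 0.00968 to 0.264. Foxa2 and microRNAs, miR-323-3p included, were not analysed here.

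Nerve injury genes formed the group with the most rises. Of the 39 measured members, 31 rose, 1 fell and 7 did not pass. The injury list had camera adjusted p = 4.74e-38, and adjusted p = 0.0782 with an estimated correlation, with 32 higher and 1 lower members adjusted over the list alone. Beside Atf3 and Cacna2d1, with log2 fold changes of 4.51 and 2.09, the members with the smallest p were the stress gene Gadd45a (2.38, from 599.9 ± 13.0 to 3140.3 ± 298) and the adhesion gene Flrt3 (2.41, from 278 ± 19.6 to 1478 ± 27.2). The member that fell was Nptx1, a secreted pentraxin of synapses (−0.42, limma adjusted p = 0.00394), named after its value was seen.

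The 12 genes with the largest rise under the naming rule included several that are almost silent in the sham ganglion. Csrp3, Reg3b and Sprr1a are also members of the nerve injury list, so they are counted there too. Csrp3, a LIM protein best known from muscle, rose from 5.75 ± 1.89 to 926 ± 376 (log2 fold change 7.06, SE 0.29), and Stac2, an adaptor of voltage-gated calcium channels, rose from 38.7 ± 4.13 to 2091 ± 32.6 (5.72, SE 0.11). Reg3b, a secreted lectin with close paralogs that could share reads, rose from 13.6 ± 5.50 to 644 ± 64.0. The epithelial genes Tgm1, a transglutaminase of the skin barrier, and Cldn4, a tight junction protein, rose from 21.2 ± 1.26 to 767 ± 87.5 and from 3.07 ± 0.370 to 223 ± 29.7. Il24, a cytokine, and Hpd, an enzyme of tyrosine breakdown, had 4 reads each over the 3 sham libraries against 273 and 304 in CCI-ION, with log2 fold changes of 5.76 and 5.70, that of Il24 being 6.54 without sham 2. For genes with 1 to 3 sham reads the ratio of size-factor-scaled reads is given with its 95% counting interval, which covers counting error only: Hamp (1 read in sham and 776 in CCI-ION, ratio 898, interval 161 to 35505), the iron hormone hepcidin, Crisp1 (1 read in sham and 460 in CCI-ION, ratio 532, interval 95.04 to 21065), Sprr1a (1 read in sham and 372 in CCI-ION, ratio 430.4, interval 76.8 to 17044), a proline-rich protein of the epidermis, En1 (2 reads in sham and 271 in CCI-ION, ratio 157, interval 43.0 to 1301), a homeobox factor, and Ucn (3 reads in sham and 243 in CCI-ION, ratio 93.7, interval 31.7 to 458), the neuropeptide urocortin. limma adjusted p ranged from 3.19e-14 for Stac2 to 5.24e-05 for Il24 among these 12.

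The 12 largest falls were smaller in size. S100g, the calcium-binding protein calbindin-D9k, fell from 405 ± 107 to 88.0 ± 13.3 (log2 fold change −2.17, SE 0.19, limma adjusted p = 1.12e-05). Adra1a, an adrenergic receptor, fell from 52.3 ± 9.61 to 13.0 ± 6.06 (−1.997), and a second locus that the files label Sytl2_1 fell from 174 ± 19.1 to 46.0 ± 11.98 (−1.92). The muscle genes Fbxo40 and Myh8 fell from 62.7 ± 17.5 to 16.7 ± 4.05 and from 80.4 ± 12.1 to 26.0 ± 5.17. The GABA-A subunit Gabrd fell from 41.1 ± 9.96 to 7.80 ± 6.27 (−2.64), a value that was −1.79 without CCI-ION 1. Smaller counts stood behind Sidt1 (−1.70, from 26.9 ± 3.87 to 8.15 ± 4.10), Slco4c1 (−1.64, from 11.5 ± 1.602 to 3.25 ± 2.00) and the ciliary gene Cfap46 (−1.98, from 11.6 ± 7.07 to 1.78 ± 0.631; −2.59 without sham 1). Those with 1 to 3 reads over the CCI-ION libraries were Sytl5 (27 reads in sham and 1 in CCI-ION, ratio of sham to CCI-ION 23.3, interval 3.85 to 956), Krt85 (28 reads in sham and 2 in CCI-ION, ratio of sham to CCI-ION 12.1, interval 3.05 to 105) and Rd3l (21 reads in sham and 2 in CCI-ION, ratio of sham to CCI-ION 9.08, interval 2.22 to 79.8). Leaving out 1 library ended the calls of Gabrd without sham 1, sham 2 or sham 3 (adjusted p 0.0551 to 0.0762), Rd3l without sham 1, sham 3, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0501 to 0.141), Cfap46 without sham 2, sham 3, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0508 to 0.1496) and Slco4c1 without sham 1, sham 2, sham 3, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0501 to 0.0948). The Sytl2_1 call did not hold where its rows were averaged or summed, nor did that of Adra1a where the first of its rows was taken, both chosen after the data were seen.

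**Figure D2:**
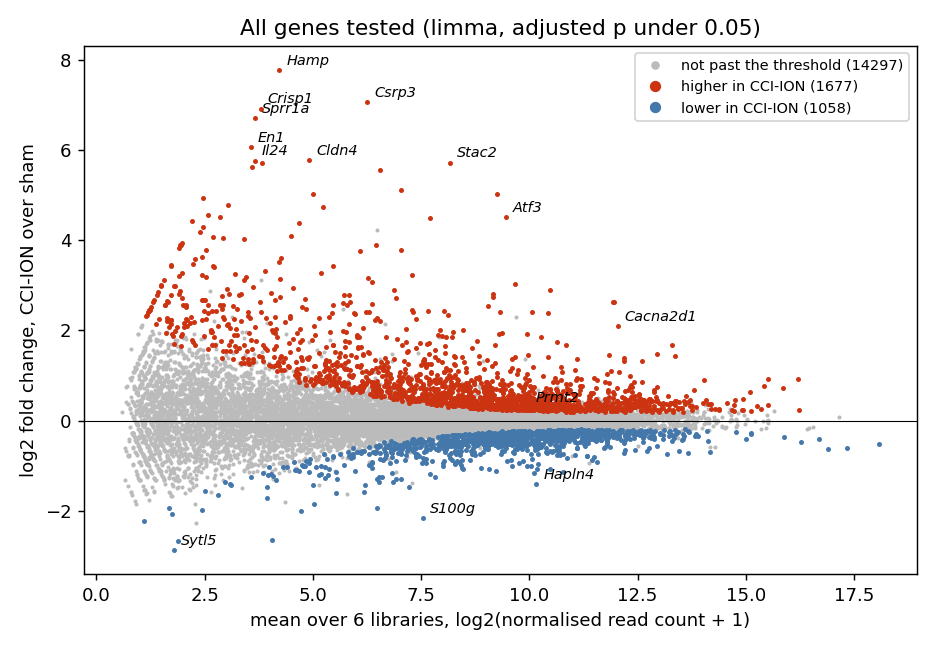
Log2 fold change of CCI-ION over sham against mean log2(normalised read count + 1) for the 17032 genes tested, with 1677 genes past the threshold and higher in red and 1058 lower in blue. The largest changes are rises of genes with low sham counts, and most falls are smaller than the largest rises.

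Voltage-gated potassium channels fell as a group. Of 47 measured pore and auxiliary subunits, 24 fell, 2 rose and 21 did not pass. The channel list had camera adjusted p = 3.90e-12, and adjusted p = 0.121 with an estimated correlation, with 3 higher and 25 lower members adjusted over the list alone. Kcnh7 (−0.95), the juxtaparanodal Kcna2 (−0.73, from 11910.2 ± 481 to 7186 ± 179.6) and the silent subunit Kcns3 (−0.82) were among the falls with the smallest p. The rises included that of the auxiliary subunit Kcne3 (0.89), named after its value was seen. In fits lacking 1 library the call ended for Kcne3 without sham 2, sham 3, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0742 to 0.135). Among the 29 other potassium channels, 5 fell and 3 rose. This list had camera adjusted p = 0.0132, and adjusted p = 0.289 with an estimated correlation, with 3 higher and 8 lower members adjusted over the list alone. The falls were Kcnj6 (−0.95), Kcnk1 (−0.55), Kcnj9 (−0.80), Kcnn3 (−0.52) and Kcnj4 (−0.92), and the rises Kcnmb4 (0.94), Kcnk13 (1.22) and Kcnk12 (0.52). Kcnk13, Kcnk12, Kcnn3 and Kcnj4 were named after their values were seen. Leaving out 1 library ended the calls of Kcnn3 without sham 2, sham 3, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0641 to 0.102) and Kcnj4 without sham 2, sham 3, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0567 to 0.0997), and the group did not pass without CCI-ION 1 and 2 (camera adjusted p = 0.199) or with the central oligodendrocyte level as a covariate (adjusted p = 0.0653, range over its alternatives 0.00402 to 0.289).

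Of 14 voltage-gated sodium channel genes, 6 fell and 2 rose. Sodium channels had camera adjusted p = 0.0124, and adjusted p = 0.269 with an estimated correlation, with the same counts adjusted over the list alone. The nociceptor channel Scn11a fell from 5566 ± 46.0 to 3962 ± 306 (−0.49), and Scn1a and Scn8a, channels of myelinated neurons, changed by −0.59 and −0.70. Scn3b, a beta subunit, and Scn3a, which is known from embryonic and injured neurons, rose by 0.94 and 0.69 on the log2 scale, Scn3a being named after its value was seen. Among 26 inhibitory receptor genes 9 fell and 3 rose. Inhibitory receptors had a test that pointed down (median −0.12), with camera adjusted p = 0.00907, and adjusted p = 0.289 with an estimated correlation. The counts were the same adjusted over the list alone. The 3 genes named next are the rises, against the direction of the list, and the 9 falls are not named here. The GABA-A subunit Gabra5 rose from 279 ± 22.8 to 757 ± 93.3 (1.43), Gabrb1 from 18.6 ± 4.85 to 99.0 ± 0.694 (2.38) and the adrenergic receptor Adra2a, named after its value was seen, by 0.73. Without CCI-ION 1 and 2, sodium channels (camera adjusted p = 0.0769, range over its alternatives 0.00675 to 0.269) and inhibitory receptors (adjusted p = 0.102, range over its alternatives 0.00310 to 0.289) did not pass. Of 23 calcium and HCN channel genes, 6 rose and 7 fell. Calcium and HCN channels did not pass as a list and had camera adjusted p = 0.489, and adjusted p = 0.730 with an estimated correlation, with the same counts adjusted over the list alone. Next to Cacna2d1, Cacnb1 rose (0.76) while the T-type channels Cacna1i and Cacna1h fell (−1.29 and −0.64).

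Markers of sensory neuron classes fell in part. Of 15 large-fibre markers 9 fell and 1 rose. Large-fibre markers had camera adjusted p = 3.50e-08, and adjusted p = 0.121 with an estimated correlation, with 1 higher and 12 lower members adjusted over the list alone. Hapln4, a matrix link protein, fell from 1853 ± 70.2 to 699 ± 13.8 (−1.40), and Nefl from 151328 ± 12464 to 98535 ± 5328 (−0.62), next to Nefm (−0.62). The exception was Spp1 (osteopontin), which rose from 12257 ± 1989.8 to 22857 ± 207 and which macrophages also express. Of 24 nociceptor markers, 7 fell and 3 rose. Nociceptor markers had camera adjusted p = 0.0102, and adjusted p = 0.345 with an estimated correlation, with 3 higher and 11 lower members adjusted over the list alone. Scn11a and the neurturin receptor Gfra2 fell (−0.49 and −0.58), and the GDNF receptor Gfra1, the artemin receptor Gfra3 and peripherin (Prph) rose (1.31, 0.65 and 0.72), Gfra3 being named after its value was seen. Without CCI-ION 1 and 2 the nociceptor list did not pass (camera adjusted p = 0.136) or with the central oligodendrocyte level as a covariate (adjusted p = 0.0625, range over its alternatives 0.00317 to 0.345). Pan-neuronal genes went both ways: of 20, 6 rose, Stmn2 (0.92) and Tubb3 (0.93) first, and 5 fell, namely Snap25 (−0.45), Avil (−0.33), Chgb (−0.25), Isl1 (−0.29) and Rbfox3 (−0.22). Chgb, Isl1 and Rbfox3 were named after their values were seen. Pan-neuronal genes did not pass as a list and had camera adjusted p = 0.958, and adjusted p = 0.985 with an estimated correlation, with 7 higher and 6 lower members adjusted over the list alone. Leaving out 1 library ended the calls of Chgb without CCI-ION 3 (adjusted p = 0.0630), Isl1 without sham 3 (adjusted p = 0.0765) and Rbfox3 without sham 2, sham 3, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0800 to 0.159). The pan-neuronal median was 0.02, turning to −0.03 after quantile normalization and −0.004 after centring.

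Of 25 macrophage markers 18 rose and 0 fell. Macrophage markers had camera adjusted p = 1.62e-12, and adjusted p = 0.240 with an estimated correlation, with 21 higher and 2 lower members adjusted over the list alone. By p, Itgam (1.49), the complement gene C1qb (1.16) and the signalling adaptor Tyrobp (1.25) came after Cd74 (2.62). Resident macrophage markers were among the 7 that did not pass over all genes, with Cd163 at −0.59 (adjusted p = 0.138), Lyve1 at −0.51 (adjusted p = 0.136) and Mrc1 at −0.01 (adjusted p = 0.990), all named after their values were seen. The Mrc1 value changes sign between alternatives, and Cd163 was lower without CCI-ION 2 (−0.82, adjusted p = 0.0260, range over its alternatives 0.0260 to 0.310). Complement had 16 rises and no falls among 21 genes. Complement genes had camera adjusted p = 1.95e-11, and adjusted p = 0.242 with an estimated correlation, with the same counts adjusted over the list alone. Rises by p were led by C3, from 124 ± 25.7 to 492 ± 38.8 (2.002), C4a (2.29) and C2 (1.67). C4a and its near copy C4b share sequence, so C4a is uncertain. Of 27 cytokine and chemokine genes 15 rose and none fell. Cytokine genes had camera adjusted p = 8.16e-07, and adjusted p = 0.133 with an estimated correlation, with the same counts adjusted over the list alone. Among them were the macrophage growth factor Csf1, from 131 ± 13.1 to 393 ± 74.4, the interleukin-1 receptor Il1r1 (1.34) and the monocyte attractant Ccl2 (1.36). Of 33 interferon-stimulated genes 9 rose and none fell, with Stat2 (0.50) and Irf7 (0.74) first. Interferon-stimulated genes had camera adjusted p = 6.26e-06, and adjusted p = 0.345 with an estimated correlation, with 14 higher and 0 lower members adjusted over the list alone. Lymphocyte markers were scarce: of 17 measured, Cd4, which rat macrophages also express, rose from 484 ± 12.9 to 858 ± 75.1, Il2rb from 9.27 ± 2.44 to 50.9 ± 21.4, and the granzyme Gzmb, at 0 reads over the sham group and 33 over CCI-ION, was at least 12.7-fold higher against a floor of 3 reads per group. Lymphocyte markers had camera adjusted p = 0.00504, and adjusted p = 0.242 with an estimated correlation, with the same counts adjusted over the list alone.

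Of 18 myelinating Schwann cell markers 4 fell and none rose. Myelinating Schwann cell markers had camera adjusted p = 1.05e-04, and adjusted p = 0.415 with an estimated correlation, with the same counts adjusted over the list alone. The groups overlapped in the mean log2 level of this list, with CCI-ION 2 (12.65) above sham 3 (12.54). The falls included those of Prx, from 37853 ± 4606 to 28392 ± 2877 (−0.41), Gldn (−0.32) and Pmp22 (−0.48). Fits lacking 1 library did not call Prx without sham 2 or CCI-ION 3 (adjusted p 0.0549 to 0.0614), Gldn without sham 1, sham 2, CCI-ION 1 or CCI-ION 3 (adjusted p 0.0533 to 0.0896) and Pmp22 without sham 2, CCI-ION 1 or CCI-ION 3 (adjusted p 0.0621 to 0.147). Of 16 genes of repair Schwann cells, 4 rose and none fell, namely Cd44 (0.68), Ncam1 (0.34), L1cam (0.23) and Runx2 (0.83). Repair genes had camera adjusted p = 0.0124, and adjusted p = 0.240 with an estimated correlation, with the same counts adjusted over the list alone. Calls ended for L1cam without sham 1, sham 3, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0518 to 0.112) and Runx2 without sham 2, sham 3, CCI-ION 1 or CCI-ION 3 (adjusted p 0.109 to 0.170). Macrophages express Cd44 too, and neurons Ncam1 and L1cam. Of 24 matrix and fibroblast genes 6 fell and 1 rose. Matrix genes had camera adjusted p = 1.43e-04, and adjusted p = 0.415 with an estimated correlation, with 1 higher and 8 lower members adjusted over the list alone. Their mean log2 level overlapped between the groups too, with CCI-ION 2 (10.53) above sham 2 (10.42). Pdgfra (−0.58) and Col14a1 (−0.47) were among the falls. The rise was that of the protease inhibitor Timp1 (1.11), named after its value was seen, and its call ended for Timp1 without sham 3, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0504 to 0.0684). Of 15 satellite glia markers, Bcan (−0.62) and the potassium channel Kcnj10 (−0.39) fell and none rose. Satellite glia markers did not pass as a list and had camera adjusted p = 0.303, and adjusted p = 0.730 with an estimated correlation, with the same counts adjusted over the list alone. Without CCI-ION 1 and 2 together that list passed downward (camera adjusted p = 0.00109, and 0.00806 with the central oligodendrocyte level as a covariate, range over its alternatives 0.00109 to 0.899).

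Central glia genes differed between libraries of the CCI-ION group. Mobp counts were 18.1, 68.8 and 6.91 in sham 1 to 3 and 296, 627 and 8.89 in CCI-ION 1 to 3. Mog counts were 78.0, 95.1 and 88.1 in sham 1 to 3 and 177, 349.9 and 94.5 in CCI-ION 1 to 3, and Gfap counts were 304, 791 and 208 in sham 1 to 3 and 2987, 4099 and 499 in CCI-ION 1 to 3. Aqp4 counts were 72.5, 133 and 35.4 in sham 1 to 3 and 309.8, 579.8 and 14.4 in CCI-ION 1 to 3, and the lineage factor Olig2 (3 reads in sham and 35 in CCI-ION, ratio 13.5, interval 4.25 to 68.6) had few reads. None of these passed in the test used here (adjusted p = 0.518 for Mobp, 0.247 for Mog, 0.267 for Gfap, 0.778 for Aqp4 and 0.277 for Olig2), and all were named after their values were seen. In alternatives some did. Gfap was higher by DESeq2 (adjusted p = 0.0489) and with the central oligodendrocyte level as a covariate (adjusted p = 0.00864), and Olig2 by DESeq2 (adjusted p = 0.0262). Without CCI-ION 3, Mog (adjusted p = 0.00334) and Olig2 (adjusted p = 0.00394) were higher, and with the covariate Aqp4 was lower (−1.15, adjusted p = 0.00480). Over all alternatives adjusted p ran from 0.00864 to 0.908 for Gfap, 0.00334 to 0.867 for Mog, 0.00394 to 0.940 for Olig2, 0.00480 to 0.993 for Aqp4 and 0.127 to 0.874 for Mobp. Of the 12 central oligodendrocyte markers, Myrf, a myelin regulator, rose (0.54) and 11 did not pass. Central oligodendrocyte markers had camera adjusted p = 0.0240, and adjusted p = 0.669 with an estimated correlation, with the same counts adjusted over the list alone. That list did not pass without sham 1 (camera adjusted p = 0.0585), sham 3 (0.123), CCI-ION 1 (0.104) or CCI-ION 2 (0.247). Gfap and Aqp4 belong to the satellite glia list too.

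**Figure D3:**
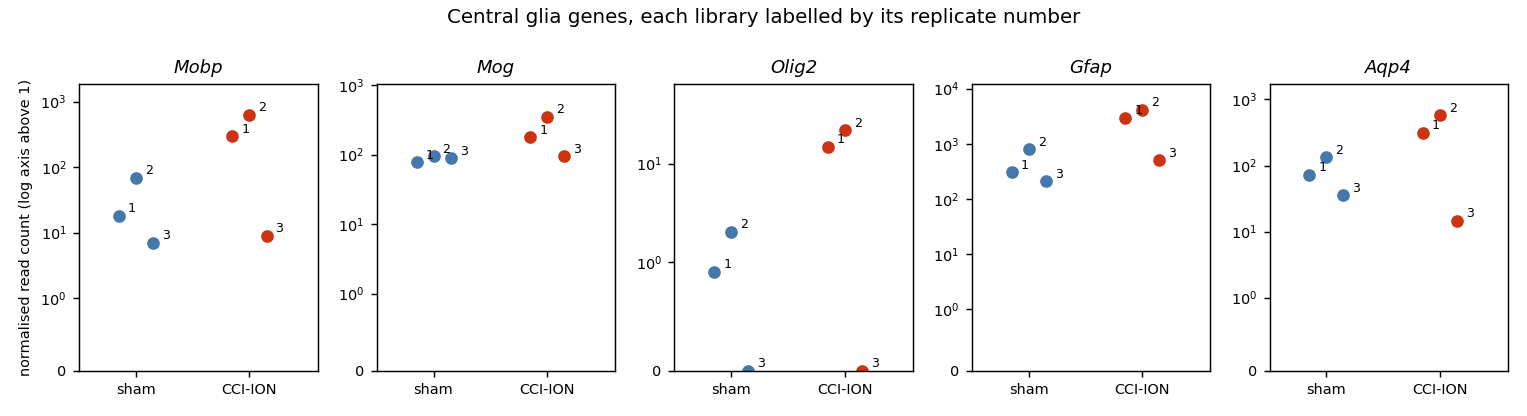
Normalised read counts of 5 central glia genes per library, numbered by replicate, on a log axis above 1 and linear below it (sham blue, CCI-ION red). CCI-ION 1 and 2 lie above the other libraries, and CCI-ION 3 lies within the sham range except for Aqp4, where it lies below each sham library.

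Immediate-early genes rose, 9 of 20 with no fall, with Csrnp1 (1.39) and Junb (1.06) first. Immediate-early genes had camera adjusted p = 6.83e-06, and adjusted p = 0.289 with an estimated correlation, with 12 higher and 0 lower members adjusted over the list alone. Of 25 cell cycle genes 4 rose and none fell. Cell cycle genes had camera adjusted p = 7.71e-04, and adjusted p = 0.345 with an estimated correlation, with the same counts adjusted over the list alone. The rises were those of the replication gene Mcm5, from 70.8 ± 15.6 to 287 ± 18.3 (2.02), and Prc1 (0.88), Tpx2 (0.51) and Cenpf (0.86). Calls ended for Tpx2 without sham 3, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0756 to 0.112) and Cenpf without sham 1, sham 2, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0768 to 0.184). Ribosomal protein genes, whose many pseudogenes make single members uncertain, rose in 15 of 31 with no fall, for example Rpl18 (0.43) and Rpl10 (0.39). Ribosomal protein genes had camera adjusted p = 1.69e-09, and adjusted p = 0.415 with an estimated correlation, with 26 higher and 0 lower members adjusted over the list alone. This list was fixed as a check of RNA quality on short transcripts, and a quality difference was not tested. Its mean log2 level was 11.65 in sham 1, 11.17 in sham 2 and 11.67 in CCI-ION 3. With the central oligodendrocyte level as a covariate, 4 members were higher.

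The other lists did not pass camera. Neutrophil markers had 2 rises and no fall among 10, Mmp9 (2.75) and Cxcr2 (2.01), with camera adjusted p = 0.217. Of 8 mast cell markers Hdc rose (1.02), with camera adjusted p = 0.887. The call was absent adjusted over the list alone, and ended for Hdc without sham 1, sham 2, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0681 to 0.173). Endothelial and mural markers had 1 fall among 19, Rgs5 (−0.46), with camera adjusted p = 0.328, and the call ended for Rgs5 without sham 1, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0605 to 0.0758). Oxidative phosphorylation had 1 fall among 33, Sdha (−0.38), with camera adjusted p = 0.360, a list that passed downward without sham 2 (0.00317), without CCI-ION 1 (0.0484) or without CCI-ION 1 and 2 together (0.00460). No erythroid gene of 10 passed (camera adjusted p = 0.280), although that list passed downward without sham 1 (0.00343). Of 21 cholesterol synthesis genes, 4 rose, including Mvd (0.37) and Fdps (0.34), 3 fell, including Stard4 (−0.58) and Hmgcs1 (−0.22), and 14 did not pass. Adjusted over the list alone 5 were higher and 3 lower, camera adjusted p was 0.841, and the call ended for Hmgcs1 without sham 3, CCI-ION 1 or CCI-ION 3 (adjusted p 0.0574 to 0.0779). Fdps and Hmgcs1 were named after their values were seen. Heat shock genes had 2 falls among 17, Chac1 (−0.48) and Hsph1 (−0.22), with camera adjusted p = 0.872. Calls ended for Chac1 without sham 2, sham 3 or CCI-ION 3 (adjusted p 0.0579 to 0.127) and Hsph1 without sham 1, sham 3, CCI-ION 1 or CCI-ION 2 (adjusted p 0.0649 to 0.112). Of 19 muscle markers Pvalb and Ttn fell (−1.15 and −1.15), Pvalb being a large-fibre marker too, and Tnnt3 rose (1.54), with camera adjusted p = 0.489. The Tnnt3 call ended for Tnnt3 without sham 2, sham 3, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0947 to 0.177). Of 11 pituitary markers, Chga, which neurons express, fell (−0.58), and growth hormone Gh1 rose (1.13), with camera adjusted p = 0.643. The Gh1 call ended for Gh1 without sham 1, sham 2, sham 3 or CCI-ION 2 (adjusted p 0.0634 to 0.154), at 0.67 without CCI-ION 2. None of 5 measured sex-linked genes passed, and none of the 13 mitochondrially encoded genes was measured. Apart from the mast cell and cholesterol lists, counts adjusted over the list alone were the same in this group of lists. Median, mean and test differed in sign for calcium and HCN channels (−0.04, 0.01, down), pan-neuronal genes (0.02, 0.09, down), satellite glia (−0.08, 0.12, down), muscle (−0.11, 0.03, down), cholesterol synthesis (−0.04, 0.01, down) and heat shock genes (0.02, 0.05, down), the median of the last being −0.03 after quantile normalization and −0.01 after centring.

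**Figure D4:**
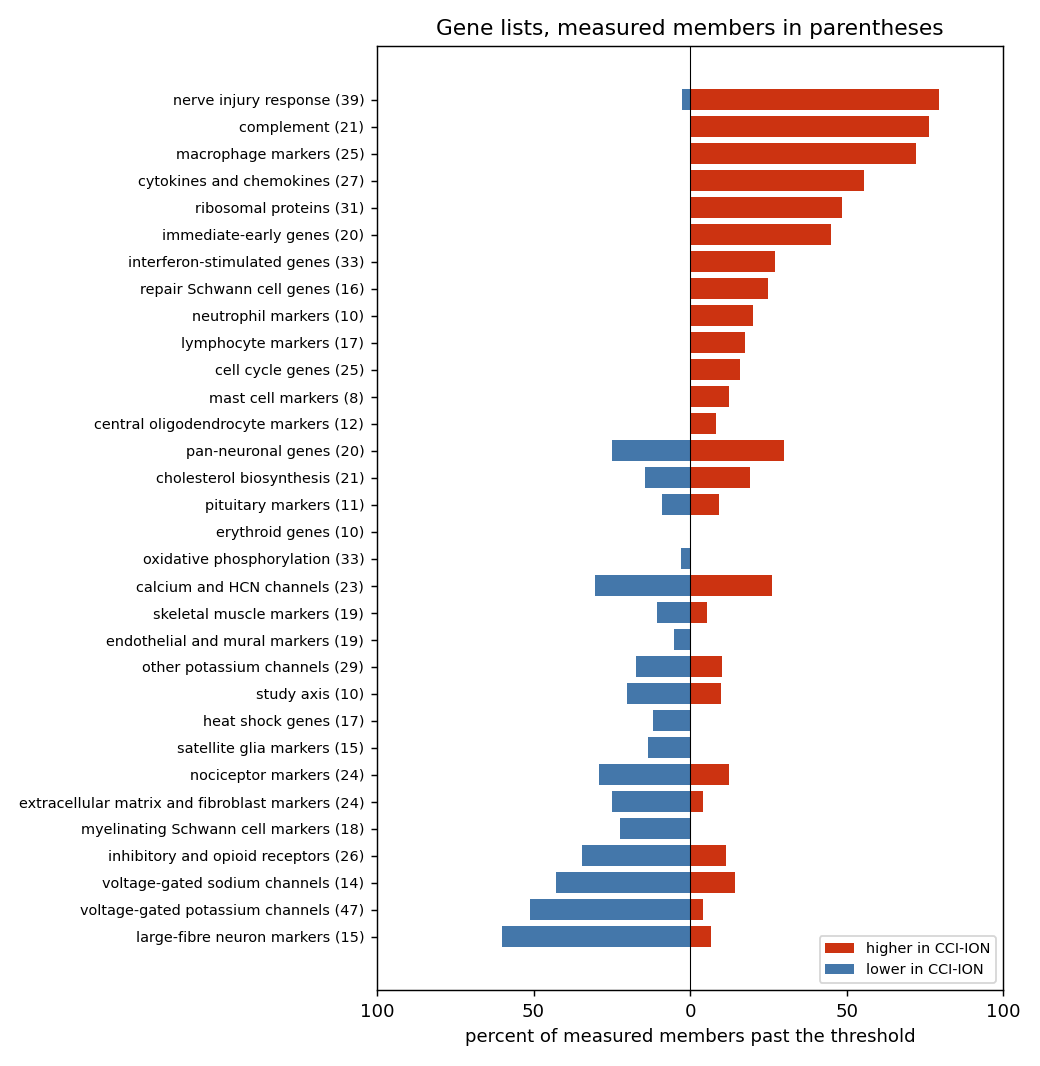
Percent of the measured members of each list that were past the threshold, higher (red, to the right) or lower (blue, to the left) in CCI-ION. Nerve injury genes reach 31 rises of 39, and voltage-gated potassium channels 24 falls of 47.

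Across all 17032 genes tested, limma called 2735 at adjusted p below 0.05, 1677 higher and 1058 lower in CCI-ION, and 549 of them changed at least 2-fold (475 higher and 74 lower). Every CCI-ION library lay on the called side of every sham library in 2716 of these genes, and 33.1% of all genes had groups apart, where chance gives 10%. Of 32 lists tested, 19 passed camera, 11 up and 8 down, 0 passed camera with an estimated correlation (6 at an unadjusted p below 0.05), and fry, which asks whether a set moves on balance one way, passed 13, 12 of them shared. The 7 that fry did not pass were sodium channels, nociceptor, myelinating Schwann cell and central oligodendrocyte markers, interferon-stimulated genes, matrix genes and ribosomal proteins, while it passed neutrophil markers (adjusted p = 0.0406). The calls were 61.3% higher, which became 50.4% after quantile normalization (1407 higher and 1384 lower). Without trend and robust settings limma called 1303 genes, and without CCI-ION 1 and 2 together, chosen after the data were seen, 900.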

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

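The alternatives chosen only after the data were seen are those that take other rows per symbol, leave out CCI-ION 1 and 2 together, or use the central oligodendrocyte level as a covariate. In the 28 alternatives with 1 value per symbol, no gene was called in the direction opposite to the 2735 calls reported. With each row tested separately, where opposite calls were not counted, 3125 symbols passed (1838 with a higher row and 1288 with a lower row), 1 of them in both directions. The count of genes past the threshold moved by more than 1.5 times in these settings: 1303 without trend and robust (909 higher and 394 lower), 549 with a fold of at least 2 (475 and 74), 900 without CCI-ION 1 and 2 (603 and 297), and 1534 with the covariate (1009 and 525). Without CCI-ION 1 and 2 the comparison is 3 libraries against 1, and the lone sample is assumed to vary like the others; the fold threshold removes genes by construction, and the cause of the other shifts was not tested. Leaving out 1 library gave 1991 to 2481 genes, 1229 to 1623 higher and 760 to 858 lower. Lists past the threshold numbered 19 in most settings, 18 to 20 without 1 library, 16 without CCI-ION 1 and 2 (14 shared), 17 with the covariate (16 shared), 13 with fry and 0 with an estimated correlation. Lost without CCI-ION 1 and 2 were sodium channels, other potassium channels, inhibitory receptors, nociceptor markers and central oligodendrocyte markers, and with the covariate other potassium channels and the last 2. The lists other than central oligodendrocyte markers that passed kept their camera calls without any 1 library. Prmt2 (0.29) kept its direction, at 0.25 to 0.32 without 1 library, and lost the threshold without trend and robust (adjusted p = 0.0662), without CCI-ION 1 and 2 (0.24, adjusted p = 0.264) and with the covariate (0.26, adjusted p = 0.0888). It did not reach a fold of 2. Its adjusted p over all alternatives ran from 0.00968 to 0.264, and the cause was not tested. Of 24 genes with the largest fold, 18 held their call in each alternative that tested them, as did 39 of 128 other called genes named, with no reversal. Genes with few reads fell below the filter in some alternatives, for example Sytl5 and Krt85, each tested in 23 of 28. Reversed values were those of uncalled genes near 0 or of central glia. Without CCI-ION 1 and 2, Mobp was −1.15, Aqp4 −2.20 and Mrc1 0.0505, and with the covariate Mobp was −0.0994, Aqp4 −1.15 (past the threshold as lower, adjusted p = 0.00480) and Mrc1 0.0226. Uncalled genes that passed in an alternative were Gfap, Mog, Olig2, Aqp4 and Cd163, as given in the report. Aqp4 was −0.0347 without CCI-ION 2 and 2.58 without CCI-ION 3. Mrc1 (−0.01) was 0.0157 by edgeR with TMM, 0.0159 by DESeq2, 0.0164 by edgeR with DESeq2 size factors, 0.0144 with library totals, 0.00981 without a filter, 0.0292 with the stricter filter, and 0.13, 0.04, 0.28 and −0.27 without sham 1, sham 3, CCI-ION 1 and CCI-ION 2. The central oligodendrocyte list pointed down without CCI-ION 1 and 2 (camera adjusted p = 0.275) and with the covariate (adjusted p = 0.819), settings that remove its difference by construction. Deviations of samples with the same number correlated at −0.115, −0.005 and 0.020, which gave no sign that the numbers pair the samples. With 3 libraries per group a weak pairing could be missed. With the replicate block limma called 2637 genes (1636 higher and 1001 lower) and 19 lists, with Prmt2 at 0.29 past the threshold. Depth limits genes with few reads, whose ratios carry wide counting intervals.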

Other observations

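The lists in the next 2 paragraphs, and the tests of a rise of central glia genes, of the macrophage explanations, of the neuronal RNA share and of large-fibre against nociceptor markers, were chosen only after the result was seen. These lists hold genes whose changes were already known when they were written, so no set test is drawn from them and the values are those of single genes. Of 27 skin barrier genes 12 rose and 2 fell. This list holds Tgm1, Cldn4 and Sprr1a, the last of which is also a member of the nerve injury list. Padi3, a peptidylarginine deiminase of hair and skin, rose from 12.6 ± 1.94 to 147 ± 35.4 (3.43) and the keratin Krt19 from 27.2 ± 10.97 to 146 ± 47.3 (2.39). The 2 falls were Cdh1 (−0.25) and Perp (−0.67), the call of Cdh1 being lost without sham 3 (limma adjusted p = 0.0506). Of 8 class II MHC genes, a list that holds Cd74, 6 rose and 0 fell. The regulator Ciita rose from 54.5 ± 11.9 to 205 ± 74.1 (1.85), RT1-Da from 542 ± 191 to 3977 ± 873 (2.91) and RT1-Db1 by 3.03. The call ended for RT1-Db1 without sham 2, sham 3 or CCI-ION 1 (limma adjusted p 0.0510 to 0.0632). RT1 genes vary between outbred rats and share reads, so single members are uncertain.

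Of the neuropeptide genes, Ucn was among the largest rises already given, and Gal, Vip and Adcyap1 are also members of the nerve injury list. Galanin (Gal) rose from 112 ± 43.3 to 3452 ± 237 (5.02), Adcyap1 (PACAP) from 1038 ± 144 to 3305 ± 179.7 (1.68), Cck from 18.2 ± 5.28 to 92.2 ± 13.9 (2.31) and Vip from 52.9 ± 37.6 to 988 ± 89.2 (4.50). The Vip value was 3.84 without sham 3, and its call ended for Vip without sham 2, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0691 to 0.0799). Of 30 neuropeptide genes 11 rose and 2 fell. The 2 falls were the granin genes Chga (−0.58) and Chgb (−0.25), the call of Chgb being lost without CCI-ION 3 (limma adjusted p = 0.0630). The other granin genes on this list did not fall past the threshold, and a granin-family member shared with the nerve injury list rose (2.63). Of 29 neuropeptide receptors 4 rose, namely Npy2r (1.23), Sstr3 (4.03) and Cckbr (3.17) and Sstr4 (2 reads in sham and 60 in CCI-ION, ratio 34.7, interval 9.20 to 293), and none fell. Sstr3 was 3.34 without sham 1. Cckbr is also a member of the nerve injury list. Sarcomere genes went both ways, with 4 rises and 9 falls among 36, Csrp3, Myh8 and Fbxo40 of the genes already given included. The rises were Csrp3, Ankrd1 (4.75, from 6.91 ± 3.37 to 198 ± 39.5), Tpm1 (0.31) and Tnnt3, and the falls included Ttn (−1.15), Myom1 (−1.14) and Mybpc1 (−1.29). Csrp3 and Ankrd1 are also members of the nerve injury list, so their rises are not separate from it. Calls ended for Tnnt3 without sham 2, sham 3, CCI-ION 1, CCI-ION 2 or CCI-ION 3 (adjusted p 0.0947 to 0.177) and Mybpc1 without CCI-ION 1 or CCI-ION 3 (adjusted p 0.0542 to 0.0621).

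Among the 10 splits of the 6 libraries, 1, the real one, reached 2735 genes, and the highest other reached 2. For lists, 1 split reached 19, and the highest other reached 15. With 10 splits no share below 0.05 can be had. The lists passed in the other splits numbered 7 to 15. Each of those splits sets 2 libraries of a group with 1 of the other against the reverse, so part of the difference between the groups stays in it.

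Central glia genes were high in CCI-ION 1 and 2, as given for Mobp, Gfap and Aqp4. A rise in each injured ganglion would need CCI-ION 3 above the shams, but its central oligodendrocyte mean minus the sham mean was −0.45 on the log2 scale, within the spread of the shams, which leaves a rise in part of the animals open. Varying amounts of central root tissue may be present. Of 22 other central glia genes, 11 (50%) were highest in CCI-ION 1 and 2, against at most 3 for any other pair of libraries. This was short of the majority set before this test was run. The 22 genes and the pair of libraries were chosen after values were seen, so the count is not independent evidence. Of those 22, Tspan2 (0.57), Ncan (0.80) and Itih3 (1.24) passed as higher. These genes lay above each sham library in CCI-ION 3 too (Tspan2 1671, 1616 and 1550 in CCI-ION 1 to 3). They are among the 11 but do not set CCI-ION 1 and 2 apart from CCI-ION 3. The count of 11 therefore overstates how many genes mark that pair. Among the shams, sham 2 had the highest counts of Mobp, Mog, Gfap and Aqp4, so these genes also varied without the injury. A rise in part of the animals and varying root tissue cannot be told apart, because dissection is not described in the sources used here.

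The rise of macrophage markers was set against technical explanations. A lower share of the other cells would raise endothelial and mural markers alike, but the macrophage mean gained 1.03 ± 0.131 (log2, SD of the difference) on theirs. Blood left in the tissue would raise haemoglobin genes, which changed by −0.14 (SE 0.326) against a macrophage median of 0.99. Both values argue against these explanations. More macrophages or more of these transcripts per cell after the injury both stay open and were not tested.

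The fall of voltage-gated potassium channels kept 94.3% of its median with the central oligodendrocyte level as a covariate, a fit added after the data were seen (−0.34, 19 genes lower), which argues against central root tissue as its cause. The channel mean fell by 0.41 relative to the pan-neuronal mean on the log2 scale (SD 0.069), and was lower in each CCI-ION library than in each sham library. The pan-neuronal median was 0.02, with 6 of 20 genes higher and 5 lower. Changes of pan-neuronal members spread widely (SD 0.388 between genes), which does not measure error between the groups. By this bound, added after the result was seen, the test could not decide. Pan-neuronal genes moved both ways, so they give no single measure of the neuronal share. A lower share of neuronal RNA therefore cannot be told apart from a change within neurons. Large-fibre markers may have fallen more than nociceptor markers: the difference of their means was lower in each CCI-ION library than in each sham library and changed by −0.29 (SD 0.031, exact permutation p = 0.1, the smallest that 3 against 3 allows).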
